A study of Mus musculus and Homo sapiens with 26 samples.

How the data were processed

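RNA-seq was measured in 6 pre-B cell libraries and ChIP-seq in 8 thymocyte and 8 NALM-6 libraries. Per the labels' protocols, pre-B cells were sorted from bone marrow by surface markers, poly(A) RNA was selected, and libraries were made with a NEBNext Ultra RNA kit. The submitters' processing notes name HISAT2 2.1.0, HTSeq 0.12.4, BWA and MACS2 2.1.1 and the builds mm10, mm9 and hg38, without giving the role of each. The deposited pre-B values are raw counts of reads per gene, whole numbers with a different total in each library. 0 rows named no gene. Whether counting used strand is not given in the sources used here, so overlapping and antisense genes, and near-identical paralogs, cannot be told apart in the counts. The deposited peak lists give, for each library separately, each peak's position, its fold enrichment as a linear ratio, −log10 of its p and q values, and its summit. Thymocyte peaks were read as mm9 from the peak names and from peak ends on chromosome 1 up to 197068094, and NALM-6 peaks as hg38. How the 4 input libraries entered peak calling is not given in the sources used here.

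Groups were taken from the sample titles. Pre-B counts were tested with edgeR 4.0.16 in R 4.3.3 (filterByExpr defaults, TMM factors, robust quasi-likelihood F test, genotype as the only term), with Benjamini-Hochberg adjustment over 11851 tested genes. SEs of log2 fold changes were taken from the F statistics, and CPM values were computed on library totals. The 22 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01 where at least 5 members were tested, which left 18, and with an estimated correlation and fry beside it. DESeq2 1.42.0 was an alternative. Named genes were Ikzf1 to Ikzf3, the 10 largest increases and 10 largest decreases among called genes with a mean log2 CPM of at least 2 and no overlap between genotypes, and up to 4 members of each list with the smallest adjusted p, some of which are not reported here. Cd3e, S100a8, Xist and Ddx3y were chosen after their values were seen. Gene symbols are those of the count table, and 11841 of the tested symbols matched a RefSeq table of assembly GRCm38.p6, used only for chromosome membership and neighbours.

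The gene test was tried on simulated counts drawn from the libraries' means, totals and dispersions, with 81, 55 and 64 genes changed 1.5-fold, 2-fold and 4-fold. For heterozygous against wild-type pre-B cells, over 11702 genes run, it recovered 67.9% of genes changed 1.5-fold, 78.2% of those changed 2-fold and 95.3% of those changed 4-fold, with 10 false calls of 169. An early version of the list test used a single unchanged list, which camera called, so 100 unchanged lists of 25 genes were drawn. At an unadjusted p under 0.05, camera called 3 of them, camera with an estimated correlation 0 and fry 5, and none was called after adjustment. The simulated genes varied independently, and far fewer were changed than were called in the data. These rates therefore do not cover lists whose genes vary together.

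Peaks on assembled chromosomes were merged over the libraries of an experiment into regions (overlap of at least 1 bp), in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and merging was checked against bedtools 2.31.1 on simulated intervals. A region counted as called in a group when every library of the group had a peak in it. Similarity was the Jaccard index over merged regions. Lists of equal length held the 5000 peaks with the highest fold enrichment per thymocyte library, and 4360, the shortest list, per NALM-6 library. Named regions were the 3 with the highest mean deposited fold enrichment in each class. Shares of regions carry 95% Wilson intervals.

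Tests, groups, lists, naming rules and most alternatives were fixed before the data were examined. The alternatives were other scaling, filters and tests for the counts, stricter peak thresholds of 5 for −log10 q or fold enrichment, equal-length lists, summits widened by 100 bp to each side, the replicate number as a block, and leaving out each library. Thinning all pre-B libraries to the smallest total, a term for libraries with more than 100 Y-linked counts, and leaving out X- and Y-linked genes were added after seeing the data. Motif and word shares at summits, peaks at transcription starts of a gene panel, and changed genes with thymic peaks were planned but not run, since no genome or annotation of builds mm9 or hg38 was used here.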

Results

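The series held 26 samples from 3 experiments on Aiolos, the zinc-finger transcription factor encoded by Ikzf3 (IKZF3 in human), and on its relative Ikaros, encoded by Ikzf1. Both proteins regulate lymphocyte development. The first experiment was RNA-seq of sorted bone-marrow pre-B cells, the B-cell precursors that precede surface IgM, from wild-type mice (3 libraries) and mice heterozygous for the Aiolos substitution G158R (3 libraries). The second was chromatin immunoprecipitation with sequencing (ChIP-seq) of thymocytes from wild-type and homozygous G158R mice, with 2 libraries per genotype for Aiolos and 2 per genotype for Ikaros. The third was anti-FLAG ChIP-seq in NALM-6, an established human pre-B leukaemia cell line, with IKZF3 knocked out and AIOLOS-WT or AIOLOS-G159R induced by 1 ng/ml doxycycline for 48 h, in 4 libraries per form. The 4 input libraries were not analysed here. Pre-B counts totalled 5689403, 5143796 and 6115774 in the wild-type libraries and 24980504, 24732411 and 27666061 in the heterozygous libraries, a 4.57-fold difference in mean depth. The labels do not say whether libraries of a group came from separate animals or cultures, so p-values measure the spread between these libraries, which may be technical. Only for the heterozygous pre-B libraries do sex-linked reads, given below, show that not all came from the same animal.

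The first comparison asked which transcripts differed between heterozygous G158R and wild-type pre-B cells. Of the genes that rose, Prdm1, which encodes the plasma cell regulator Blimp-1, went from 8.37 ± 1.28 CPM (counts scaled to the library total; SD, n = 3) to 81.0 ± 15.8, and Sema4g, a semaphorin, went from 1.07 ± 0.0934 to 117 ± 55.9 CPM. Of the genes that fell, Fosb and Fos, both AP-1 transcription factors of the immediate-early response, went from 72.8 ± 29.4 to 0.543 ± 0.184 CPM and from 63.6 ± 24.5 to 3.75 ± 2.28 CPM. Transcripts of the mutated gene itself were at 775 ± 5.69 CPM in wild-type and 714 ± 11.4 CPM in heterozygous cells, and Ikzf3 was not called (log2 fold change -0.12, SE 0.06, adjusted p = 0.102, edgeR quasi-likelihood test). Ikzf1 was at 1446 ± 15.9 and 1424 ± 103 CPM (adjusted p = 0.773). Ikzf2, which encodes Helios, was near the floor at 0.748 ± 0.499 and 0.954 ± 0.364 CPM.

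Among 11851 genes tested of 25237 in the table, 4176 changed at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 2134 higher and 2042 lower in heterozygous cells. Of these, 858 changed by at least 1 on the log2 scale, 336 higher and 522 lower. Genes were named by size of change among called genes with a mean log2 CPM of at least 2 and no overlap between genotypes, which chance gives for 10% of genes in 3 against 3 libraries. The largest increases by this rule after Sema4g (log2 fold change 6.76, SE 0.86, adjusted p = 0.00581) were in Rasd1, a Ras-related GTPase (4.66, SE 0.29), Smoc1 (3.76, SE 0.27), Adamts14 (3.36, SE 0.19), Slc6a19, a neutral amino acid transporter (3.28, SE 0.24), and Prdm1 (3.27, SE 0.18, adjusted p = 3.38e-07). Serpina3g (2.91, SE 0.33), the inhibitory receptor gene Pirb (2.86, SE 0.24), the Fc receptor-like gene Fcrl6 (2.82, SE 0.50, adjusted p = 0.0135) and Cdkn1c, a cell cycle inhibitor (2.96, SE 0.77, adjusted p = 0.0445), completed the 10 largest increases. Cdkn1c lost its call without wild-type replicate 1, 2 or 3 (edgeR adjusted p = 0.142, 0.134 and 0.151), without heterozygous replicate 3 (0.0862) and with no filter on low counts (0.0677), at log2 fold changes of 2.85, 2.92, 3.14, 3.07 and 2.98 and in a range of 1.57e-05 to 0.151 over all settings. Fcrl6 lost its call without wild-type replicate 2 (edgeR adjusted p = 0.0537) or 3 (0.0788), at log2 fold changes of 2.72 and 2.70 and in a range of 3.77e-09 to 0.0788.

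By the same rule, the largest decreases after Fosb (log2 fold change -7.05, SE 0.45, adjusted p = 0.000138) were in Rgs10, a regulator of G-protein signalling (-4.85, SE 0.25), Arhgef39 (-4.69, SE 0.22), the actin nucleator gene Fmn2 (-4.18, SE 0.14), Fos (-4.09, SE 0.55, adjusted p = 0.00622) and the adhesion receptor gene Ceacam1 (-3.98, SE 0.11, adjusted p = 9.16e-11). Tmprss3 (-3.66, SE 0.17), Eps8l2 (-3.42, SE 0.26), Galnt10 (-3.19, SE 0.21) and Golim4 (-3.06, SE 0.16) followed. Ceacam1 went from 76.5 ± 6.39 to 4.87 ± 0.404 CPM and Tmprss3 from 90.5 ± 1.35 to 7.18 ± 2.14 CPM (SD, n = 3).

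**Figure D1:**
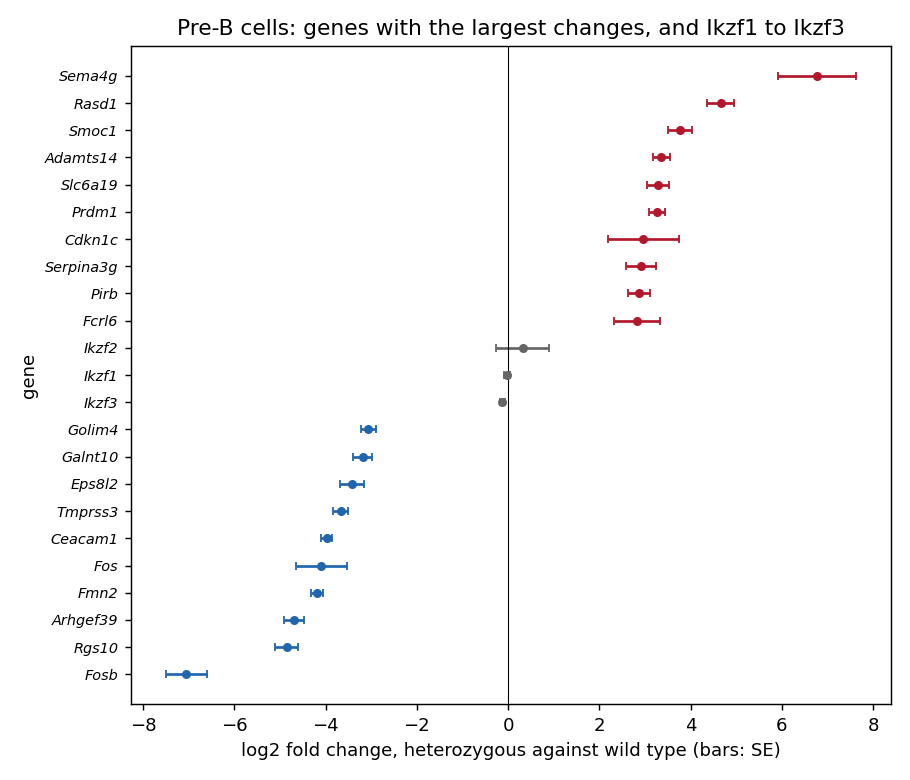
Log2 fold change of heterozygous against wild-type pre-B cells (x axis) for each gene (y axis), as points with SE bars, n = 3 libraries per genotype; the 10 largest increases are red, the 10 largest decreases blue, and Ikzf1, Ikzf2 and Ikzf3 grey. The genes shown run from -7.05 for Fosb to 6.76 for Sema4g, and Ikzf3 lies at -0.12.

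The libraries differed in more than genotype. Xist, the transcript of the inactive X chromosome, was at 4030 to 4337 CPM in the 3 wild-type libraries and 3638 CPM in heterozygous replicate 2, against 1.20 and 4.45 CPM in heterozygous replicates 1 and 3. Those 2 libraries carried the Y-linked Ddx3y at 205 and 185 CPM, and the other 4 carried none. With a term for the libraries with Y-linked reads, added after seeing the data, 3758 genes were called, 3163 of them among the 4176. This fit, called the Y-term fit, rests on heterozygous replicate 2 alone against 3 wild-type libraries, so its differences from the other fits cannot be separated from that library, which is assumed to vary like the others. Its log CPM values correlated at 0.985 and 0.984 with heterozygous replicates 1 and 3, which correlated at 0.991 with each other. Wild-type pairs correlated at 0.987, but at a lower depth, where counting error also lowers correlation. Set against counting error, count differences between heterozygous replicate 2 and replicates 1 and 3 had a chi-square per degree of freedom of 25.5 and 25.3. Between replicates 1 and 3 it was 8.82, so heterozygous replicate 2 lay further from those libraries than they did from each other.

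Gene lists fixed beforehand were then examined, against a background of 2134 genes that rose and 2042 that fell among all 11851 tested. Calls in both directions within a list are therefore no trait of that list by themselves. Of 24 tested immediate-early and stress genes, 9 fell and 3 rose: Jund fell by 1.35 on the log2 scale, Klf4 by 2.80 and Dusp1 by 1.05, while the heat-shock gene Hspa1b rose by 2.31. Of 28 interferon-response genes, 11 fell and 4 rose, with the antiviral genes Mx1 (-3.16), Mx2 (-2.97), Dhx58 (-2.28) and Ifit2 (-1.61) among those that fell. Adjusted over the list alone, 11 fell and 3 rose in the first list, and 11 fell and 6 rose in the second. No list of the 18 tested passed the camera test at an adjusted p under 0.05, with 3 at an unadjusted p under 0.05, 0 with an estimated correlation and 5 by fry, which tests whether a list moved on balance in 1 direction. Those 5 were the lists for ribosomal proteins, glucose and energy, Notch, apoptosis and T-cell markers (fry adjusted p = 0.0391, 0.0444, 0.0425, 0.00564 and 0.0444). With the replicate number as a block, fry called none of these 5 (adjusted p = 0.104, 0.166, 0.0779, 0.0622 and 0.104), with mean log2 fold changes of 0.11, 0.16, -0.32, -0.14 and -0.75 against 0.11, 0.16, -0.30, -0.14 and -0.72 without the block. The glucose list also lost its fry call after thinning (adjusted p = 0.151, mean 0.15), and the glucose and T-cell lists lost theirs in the Y-term fit of heterozygous replicate 2 (adjusted p = 0.124 and 0.156), with mean log2 fold changes of 0.21 and -0.67. With at least 10 CPM in 3 libraries, fry adjusted p was 0.910 for the Notch list (mean -0.03, 8 genes) and 0.0809 for the glucose list (mean 0.07). Without heterozygous replicate 1 it was 0.0708 for the glucose list (mean 0.18). The ribosomal and apoptosis lists kept their fry calls in both settings. The immediate-early list had camera adjusted p = 0.0767, and adjusted p = 0.914 with an estimated correlation. Its camera adjusted p was 0.0333 without heterozygous replicate 1, 0.00162 with at least 10 CPM in 3 libraries, 0.0238 after thinning to equal depth, 0.00474 in the Y-term fit of heterozygous replicate 2 and 0.0256 with the replicate number as a block, in a range of 0.00162 to 0.353 over the settings at the preset correlation. With an estimated correlation, the adjusted p in these 5 settings was 0.831, 0.787, 0.904, 0.854 and 0.955. The interferon list had camera adjusted p = 0.261, and 0.0333 without heterozygous replicate 1, in a range of 0.0333 to 0.886 over the settings at the preset correlation. With an estimated correlation, the adjusted p of the interferon list was 0.914, and 0.831 without heterozygous replicate 1.

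B-lineage genes moved in both directions, as did the tested genes as a whole, of which 4176 of 11851 were called. The share of called genes was higher in these lists. Only 9 of 22 receptor signalling genes, 10 of 25 small pre-B genes and 11 of 22 pro-B list genes were not called. No test of these shares was run. Of 22 genes of pre-B-cell receptor signalling, 7 rose and 6 fell (8 and 6 adjusted over the list alone), with the surrogate light chain gene Igll1 lower by 2.87-fold, from 102 ± 15.9 to 36.0 ± 5.80 CPM, the adaptor gene Pik3ap1 lower (log2 fold change -0.83) and the kinase gene Pik3cd higher (0.51). Of 25 genes of small pre-B differentiation, 7 rose and 8 fell (9 and 8 adjusted over the list alone): Cd22 rose from 222 ± 8.11 to 488 ± 24.7 CPM and Il2ra from 248 ± 15.4 to 406 ± 28.9 CPM, whereas the recombinase gene Rag2 fell from 172 ± 18.9 to 96.1 ± 7.29 CPM and Btg2 from 464 ± 72.5 to 230 ± 14.6 CPM. Of 22 tested pro-B, large pre-B and IL-7 genes, 4 rose and 7 fell (5 and 7 adjusted over the list alone), among them Erg (1.88), Spn (-1.63), Igfbp4 (-2.78) and Lmo2 (-1.94). The median log2 fold change of the small pre-B list was -0.01 and its mean 0.03. In the Y-term fit of heterozygous replicate 2, 7 pro-B, large pre-B and IL-7 genes rose and 7 fell, the median of that list was 0.10 against -0.13 in all libraries, and that of the small pre-B list 0.20. With genotype as the only term, camera adjusted p was 0.863 for the receptor signalling list, 0.880 for the small pre-B list and 0.676 for the pro-B list. Camera tests a net shift of a list, so these values do not measure change in both directions.

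Adhesion and survival genes also moved in both directions, like the tested genes as a whole. Of 28 adhesion genes 14 were not called, and of 20 apoptosis genes 10, again a higher share of calls than over all tested genes. Of 28 tested adhesion and integrin genes, 9 rose and 5 fell (10 and 6 adjusted over the list alone), with Itgb3 higher by 2.87-fold and Ctnnd1 by 2.90-fold, and Selplg lower (log2 fold change -1.18). Of 20 tested apoptosis genes, 5 rose and 5 fell, the same numbers when adjusted over the list alone: Bmf (-1.01), Bak1 (-1.31) and Bcl2l1 (-0.77) fell and Bbc3, which encodes Puma, rose (1.32). Without heterozygous replicate 1, 2 of 19 tested apoptosis genes rose and 6 fell. Of 12 tested Notch genes, 3 fell and 1 rose, again the same when adjusted over the list alone, with Heyl at -4.10, Hes1 at -0.65, Notch2 at -0.64 and Il2ra at 0.70. Hes1 lost its call in the Y-term fit of heterozygous replicate 2 (log2 fold change -0.42, edgeR adjusted p = 0.0784). The Notch list had a median log2 fold change of 0.13 and a mean of -0.30, whereas the median was -0.03 after thinning and -0.27 in the Y-term fit of heterozygous replicate 2. At least 10 CPM in 3 libraries left 8 of its genes, with a mean of -0.03. With genotype as the only term, camera adjusted p was 0.676 for adhesion, 0.676 for apoptosis and 0.824 for Notch genes.

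Of 30 ribosomal protein genes, 12 rose and 4 fell (13 and 4 adjusted over the list alone), with Rpl7 at 0.61 and Rpl11 at 0.53 among those that rose (camera adjusted p = 0.206). Of 23 tested glucose and energy genes, 7 rose and 3 fell (8 and 3 adjusted over the list alone), including the glycolytic genes Gapdh (0.88) and Eno1 (0.52), and Hk1 (-1.13; camera adjusted p = 0.461). Of 33 cell cycle genes, 5 rose and 12 fell (6 and 12 adjusted over the list alone), with Pcna at 0.37 and Cenpe at -0.44, whereas 5 rose and 4 fell in the Y-term fit of heterozygous replicate 2. Of 24 oxidative phosphorylation genes, 2 rose and 3 fell (1 and 3 adjusted over the list alone), with Cox5a at 0.36 and Ndufa4 at -0.36. Of 15 genes of MHC class II presentation, 2 rose and 3 fell, the same when adjusted over the list alone, with the costimulatory gene Cd86 at 2.24 and H2-Oa at -1.01, which lost its call in the Y-term fit of heterozygous replicate 2 (log2 fold change -0.70, edgeR adjusted p = 0.0801). In that fit 4 of these genes rose and 1 fell. With genotype as the only term, the camera adjusted p-values of the last 3 lists were 0.676, 0.676 and 0.875. Of the 4 tested Ikaros-family genes, 0 were called by edgeR, by DESeq2 or when adjusted over the list alone, with 1, Ikzf3, at an unadjusted edgeR p under 0.05.

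Markers of other cell types were mostly near the floor. Cd3e was at most 0.243 CPM and S100a8 at most 0.352 CPM in any library. Of 8 tested plasma cell markers, 5 rose and 2 fell, the same when adjusted over the list alone: Prdm1 rose and Mzb1 rose from 127 ± 5.82 to 218 ± 22.8 CPM, while Sdc1, which encodes CD138, fell from 80.2 ± 9.43 to 19.1 ± 1.12 CPM and Slamf7 fell (-0.94). Of 15 tested markers of immature and mature B cells, 3 rose and 5 fell (4 and 5 adjusted over the list alone), with Tnfrsf13c, the BAFF receptor gene, lower (-1.25), and Cd55 lower (-0.66). Of 7 tested T-cell markers, 3 fell and 0 rose (3 and 1 adjusted over the list alone), namely Lck (-1.65), Zap70 (-1.44) and Tcf7 (-1.49). Tcf7 lost its call in the Y-term fit of heterozygous replicate 2 (log2 fold change -0.73, edgeR adjusted p = 0.0997). With genotype as the only term, camera adjusted p was 0.676 for plasma cells, 0.676 for immature and mature B cells and 0.461 for T cells. Of the remaining marker lists, with the same counts when adjusted over each list alone, 1 of 2 tested NK and innate lymphoid genes rose (Prf1, 3.91), 2 of 4 myeloid genes rose (Tyrobp, 1.25, and Itgam, 0.35), 1 of 4 erythroid genes fell (Car2, -1.41), 2 of 8 dendritic cell genes rose (Cox6a2, 1.73, and Cst3, 0.22) and 1 of 6 stem and progenitor genes rose (Angpt1, 1.10). Itgam lost its call without wild-type replicate 1 or 3 or heterozygous replicate 1 or 2 (edgeR adjusted p = 0.0968, 0.0615, 0.0519 and 0.0724, at log2 fold changes of 0.28, 0.35, 0.35 and 0.26) and after thinning (0.265, at 0.18). Cst3 lost its call without wild-type replicate 1 or 2 or heterozygous replicate 2 or 3 (edgeR adjusted p = 0.0961, 0.116, 0.0772 and 0.0870, at log2 fold changes of 0.19, 0.21, 0.17 and 0.20) and by DESeq2 (0.0527, at 0.22). Camera adjusted p was 0.875 for the dendritic cell list, whose median log2 fold change was -0.09 and mean 0.03, and 0.849 for the stem and progenitor list. The NK, myeloid and erythroid lists had too few tested genes for camera. Prf1 was near the floor in wild-type cells, at 0.447 ± 0.629 CPM against 6.41 ± 2.52 CPM in heterozygous cells (SD, n = 3).

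The second comparison asked how Aiolos and Ikaros occupancy differed between wild-type and homozygous G158R thymocytes. Most wild-type regions were also called in homozygous cells: of 46243 merged regions called in both wild-type Aiolos libraries, 72.8% (95% Wilson interval 72.4 to 73.2) were called in both homozygous Aiolos libraries and 13.0% in neither. For Ikaros, 60.1% (59.6 to 60.6) of 39654 wild-type regions were called in both homozygous libraries and 10.7% in neither. In the reverse direction, 79.3% of 42475 homozygous Aiolos regions and 91.7% of 26005 homozygous Ikaros regions were called in both wild-type libraries. Peak numbers were 97618 and 101975 for wild-type Aiolos, 77368 and 86404 for homozygous Aiolos, 96426 and 81384 for wild-type Ikaros, and 85708 and 44987 for homozygous Ikaros.

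The mean log2 ratio of peak numbers, homozygous to wild-type, was -0.29 for Aiolos and -0.51 for Ikaros, and with 2 libraries per group an exact two-sided permutation test within 1 antibody could not give a p below 0.333. Without homozygous Ikaros replicate 2, the Ikaros ratio was -0.05. Covered length was 71.5 ± 12.4 Mb in wild-type and 70.2 ± 9.60 Mb in homozygous Aiolos libraries (SD, n = 2), and 54.3 ± 1.48 and 46.0 ± 24.97 Mb for Ikaros. Intervals on shares cover counting error only and not the spread between 2 libraries.

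Regions of Ikaros and Aiolos were compared within each genotype. In wild-type thymocytes, 86.2% of Ikaros regions were called in both Aiolos libraries and 73.9% of Aiolos regions in both Ikaros libraries. In homozygous thymocytes the shares were 94.7% and 58.0%. Homozygous Ikaros replicate 2 had the shortest list, with 44987 peaks. In equal-length lists the shares were 83.0% and 77.9% in wild-type and 81.7% and 73.5% in homozygous cells. There the Ikaros share was not higher in homozygous cells, so the full-list contrast cannot be told apart from list length. The shares moved when a library was left out. Leaving out 1 of 2 libraries also loosens the requirement of a call in both, so these moves do not measure the weight of that library alone. Wild-type Aiolos regions, for example, numbered 46243 with both libraries and 82145 without replicate 1. The wild-type Aiolos share in homozygous cells was 46.8% without wild-type Aiolos replicate 1, the wild-type Ikaros share 36.9% without wild-type Ikaros replicate 2, and the homozygous Ikaros share in wild-type cells 55.9% without homozygous Ikaros replicate 2. For the overlap of Ikaros and Aiolos regions in wild-type cells, the Ikaros share was 55.8% without Ikaros replicate 2 and the Aiolos share 45.5% without Aiolos replicate 1. In homozygous cells, the corresponding shares were 62.7% and 89.4% without Ikaros replicate 2, and the Aiolos share was 39.5% without either Aiolos library and 49.0% with summit-based regions.

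The strongest regions separated the genotypes more than the full lists. With 5000 peaks per library, the Jaccard index was 0.628 between the wild-type Aiolos libraries, 0.652 between the homozygous Aiolos libraries and 0.401 on average between Aiolos libraries of different genotype. Homozygous Ikaros libraries shared a mean Jaccard index of 0.602 with homozygous Aiolos libraries and 0.447 with wild-type Ikaros libraries. The within-genotype minus between-genotype Jaccard index was 0.186 in these lists and 0.0311 in the full lists, and in both the real split was the highest of 18 splits within antibody (exact one-sided permutation p = 0.0556, the smallest these libraries can give). In the full lists the real split lost this rank when any Aiolos library was left out. Without wild-type Aiolos replicate 1 or 2 or homozygous Aiolos replicate 1 or 2, the real split gave 0.0299, 0.0293, 0.02895 and 0.0255. The highest other split gave 0.0388, 0.0385, 0.0293 and 0.0411 (exact one-sided permutation p = 0.111 each), against 0.0159 with all libraries. The other splits thus moved more than the real one, and they then set 1 Aiolos library against 2. Libraries were not left out of the equal-length lists.

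Regions restricted to 1 genotype included the same interval for both proteins. On mouse build mm9, chromosome 3 from 119221988 to 119222330 was called only in wild-type libraries, with a deposited fold enrichment of 38.0 ± 16.3 for Aiolos and 40.9 ± 3.84 for Ikaros (SD, n = 2). Chromosome 17 from 86821977 to 86827679 was called only in homozygous libraries, at 46.7 ± 17.2 for Aiolos and 27.1 ± 2.20 for Ikaros. The other strongest wild-type-only Aiolos regions lay on chromosome 1 from 167283484 to 167283963 and chromosome 9 from 87990821 to 87992094, and the homozygous-only ones on chromosome 19 from 51374950 to 51375350 and chromosome 2 from 172461173 to 172462127. For Ikaros, chromosome 9 from 39960098 to 39963381 and chromosome 4 from 55800856 to 55801168 were called only in wild-type libraries, and chromosome 3 from 121311272 to 121313100 and from 67735053 to 67737141 only in homozygous libraries. These last regions had 20.3 ± 16.1 and 18.1 ± 18.5, with 8.90 and 5.00 in the lower library, so their rank rested on 1 library. The homozygous-only Aiolos regions on chromosomes 19 and 2 also varied widely, at 34.6 ± 22.4 and 29.1 ± 15.5. No annotation of build mm9 was used here, so genes at these positions are not named.

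**Figure D2:**
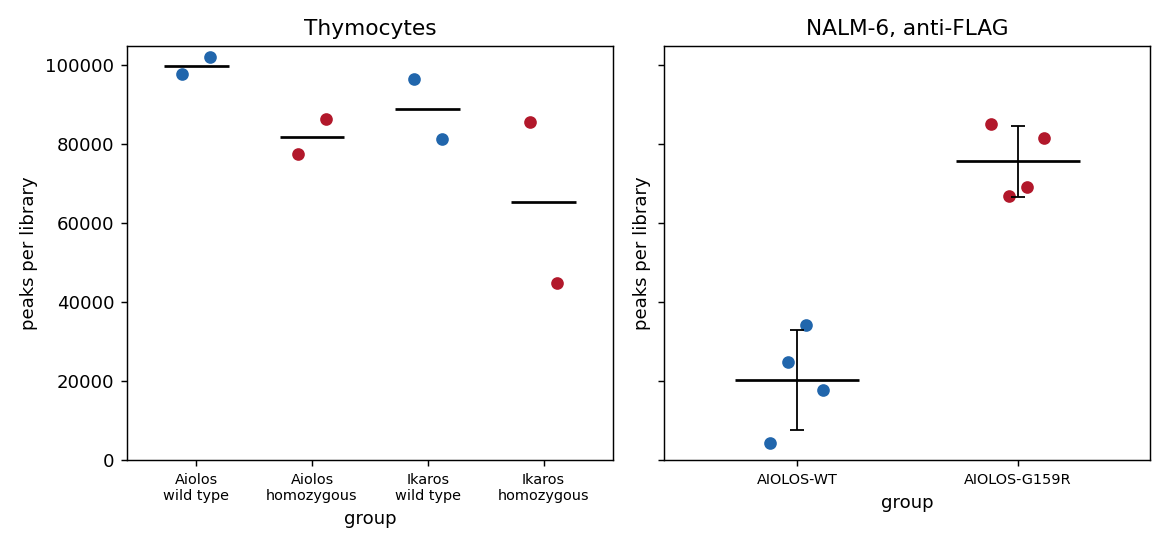
Number of peaks per library (y axis, from 0) by group (x axis) for thymocytes, left, and NALM-6 cells, right; points are libraries, horizontal lines means, and bars in the NALM-6 panel the SD of 4 libraries. The 4 AIOLOS-G159R libraries hold 66809 to 84979 peaks and the 4 AIOLOS-WT libraries 4360 to 34290.

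The third comparison asked where AIOLOS-WT and AIOLOS-G159R bound in NALM-6 cells lacking endogenous AIOLOS. Libraries of the G159R form held more peaks than those of the WT form, with means of 75600 ± 8950 and 20359 ± 12605 peaks (SD, n = 4). On merged regions, 21322 were called in all 4 G159R libraries and no WT library, 87 in all 4 WT libraries and no G159R library, and 3481 in all 8. Of the regions in each WT library, 92.4% to 97.7% were called in at least 1 G159R library, whereas 32.3% to 42.5% of the regions in each G159R library were called in at least 1 WT library. Regions numbered 3703 to 25521 per WT library and 54103 to 74451 per G159R library. The shorter WT lists limit the G159R shares, so this asymmetry does not show how many G159R regions WT left unbound.

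The mean log2 number of peaks was higher by 2.23 with G159R, a 4.68-fold ratio (exact two-sided permutation test over 70 assignments, p = 0.0286, the smallest they can give). Without any 1 of the 4 G159R libraries the exact permutation p was 0.0571 and the log2 difference 2.17 to 2.28. Covered length was 66.4 ± 7.51 Mb with G159R and 10.8 ± 7.36 Mb with WT (SD, n = 4). Depth is not given in the peak lists, and the number of called peaks moves with it. AIOLOS-WT replicate 1 had 4360 peaks, and without it the log2 difference was 1.60 (exact permutation p = 0.0286), 282 regions were restricted to WT and 12537 were called in all libraries.

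Libraries of 1 form shared regions more than libraries of different form. The mean Jaccard index was 0.644 between G159R libraries, 0.412 between WT libraries and 0.220 between forms, and the within-form minus between-form difference of 0.308 was the highest of 35 splits (exact one-sided permutation p = 0.0286). With 4360 peaks per library, 1727 regions were in the shortened lists of every G159R and no WT library. Another 1083 were in those of every WT and no G159R library, and 925 in all 8. A region missing from a shortened list may still be called in the full list, where 87 regions were restricted to WT. In the shortened lists, the mean Jaccard index was 0.787 between G159R libraries, 0.593 between WT libraries and 0.231 between forms. With fold enrichment of at least 5, 10984 regions were restricted to G159R, with −log10 q of at least 5 the number in all 8 libraries was 2248, and with summit-based regions 386 were restricted to WT.

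The strongest G159R-only regions lay, on human build hg38, on chromosome 15 from 90651510 to 90656455 with a deposited fold enrichment of 75.4 ± 6.59 (SD, n = 4), on chromosome 1 from 226952324 to 226959198 with 74.6 ± 6.86, and on chromosome 5 from 1971464 to 1975837 with 69.4 ± 4.83. The strongest WT-only regions lay on chromosome 20 from 48448529 to 48451705 with 36.8 ± 16.0, chromosome 2 from 111943480 to 111945311 with 30.7 ± 11.9, and chromosome 4 from 183850342 to 183853077 with 30.7 ± 13.6. Regions called in all 8 libraries were led by chromosome 4 from 1043416 to 1057905 with 64.5 ± 20.6 (SD, n = 8), and by chromosome 17 from 43270581 to 43271744 and from 43294303 to 43297814. No annotation of build hg38 was used here, so genes at these positions are not named.

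**Figure D3:**
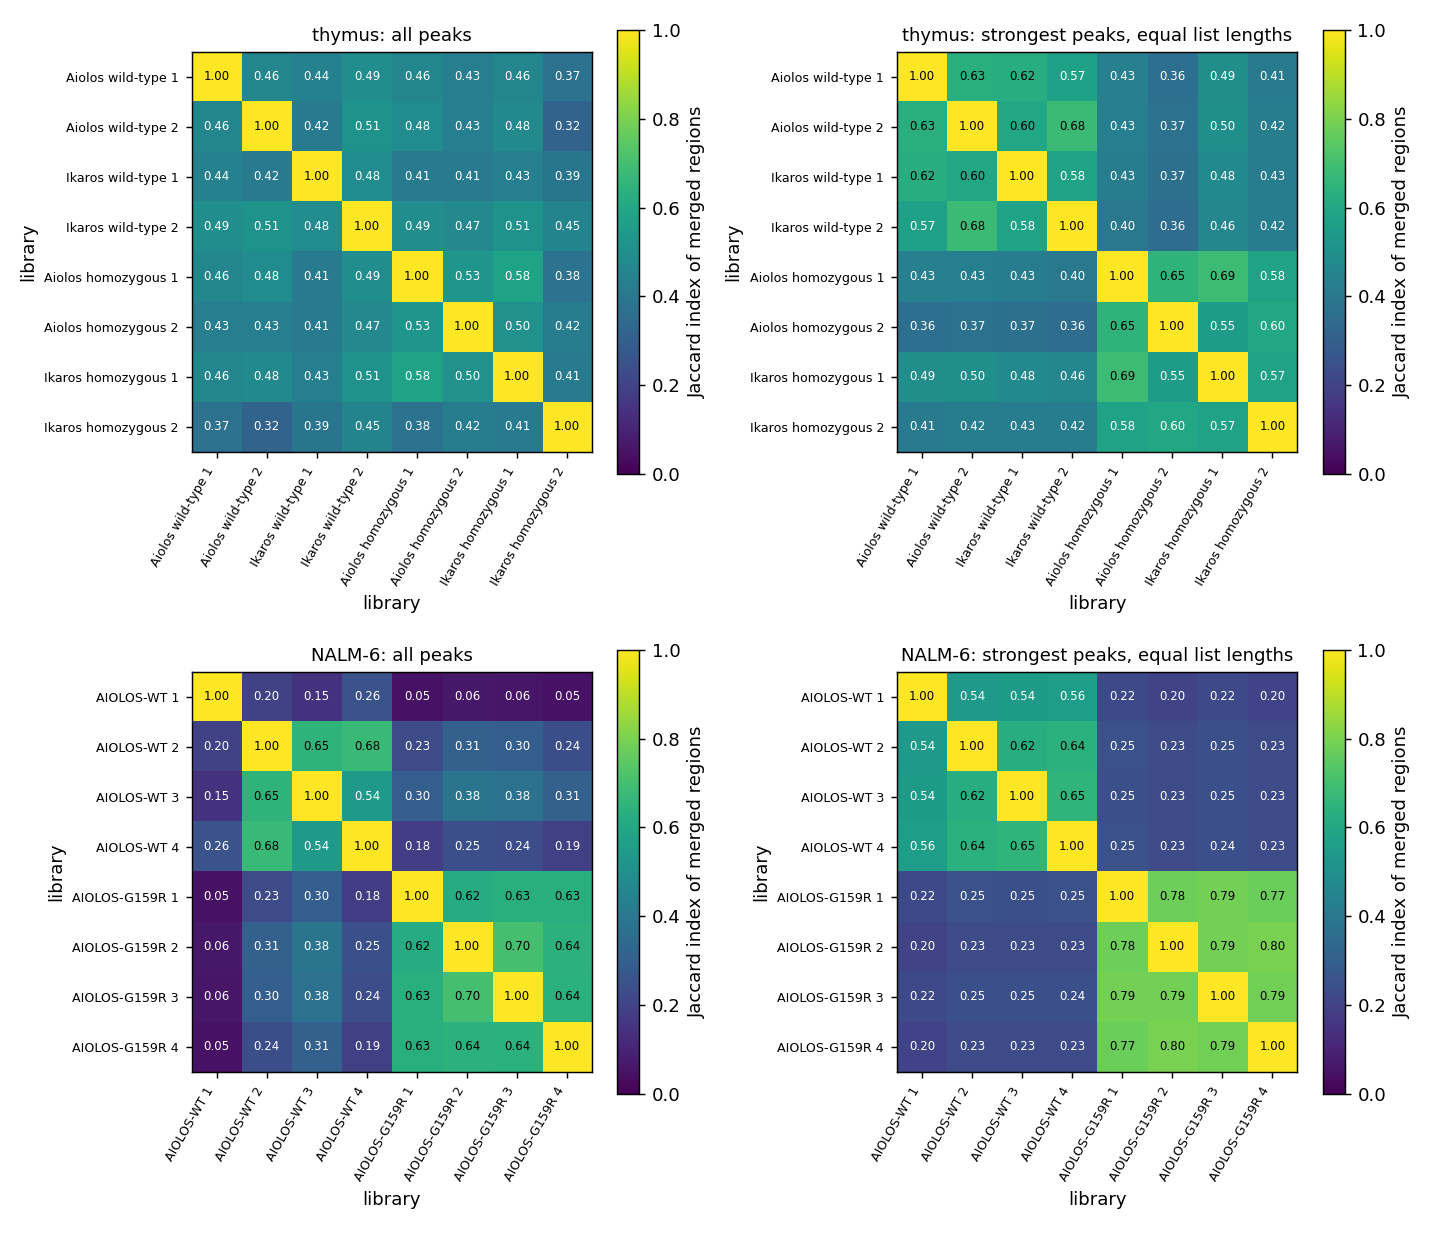
Jaccard index of merged regions (colour, from 0 to 1, printed in each cell) for each pair of libraries on both axes, for thymocytes (top) and NALM-6 (bottom), with all peaks (left) and with the strongest peaks in lists of equal length (right). In the equal-length NALM-6 lists, pairs of the same form lie between 0.540 and 0.800 and pairs of different form between 0.202 and 0.249.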

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

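Thinning, the term for Y-linked reads, the ratio of totals and the sharing of restricted regions between antibodies were chosen as tests after the results were seen, whereas comparisons with other splits and lists of equal length were fixed before but set against explanations only afterwards. Among 12 screened measures of the NALM-6 groups, 1 stood apart by the gap to its neighbours: the highest fold enrichment of AIOLOS-G159R replicate 1 was 93.6, against 75.2 to 76.9 in the other G159R libraries. Chance marks about 1 group in 20 in this way. Peaks on contigs outside the assembled chromosomes, which no comparison used, numbered up to 416 (AIOLOS-WT replicate 3) and made up 0.354% to 2.35% of each NALM-6 list.

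The first pattern is the 4176 genes changed in pre-B cells. The depth gap argues poorly as the whole cause: after thinning to the smallest total, 82.2% of these genes were still called with the same sign. Sex of the animals cannot be told apart from genotype: beside a term for libraries with Y-linked reads 75.7% were still called with the same sign, but that fit rests on heterozygous replicate 2 alone. A preparation or sequencing batch cannot be told apart either, since the smallest heterozygous total was 4.04 times the largest wild-type total and the labels give no batch, and the mutation stays an untested biological explanation. The real split called 4176 genes and the highest other 0 (1 of 10 splits as large), and 10 splits are too few for a share under 0.05.

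The second pattern is the NALM-6 libraries. In lists of equal length the within-form minus between-form Jaccard index was 0.459, against 0.0765 for the highest other split, which argues against list length as the source of the separation. In the full lists it was 0.308, with 0.0938 for the highest other. There 1 of 35 splits was as large, the smallest share that 35 splits can give. This argues against chance only if the libraries are independent, which the labels do not say, and a preparation shared within a form was not tested. The excess of regions restricted to G159R over those restricted to WT was 245-fold in the full lists, 75.6-fold without AIOLOS-WT replicate 1, 50.04-fold with summit-based regions and 1.59-fold at equal length. Equal length itself bounds that ratio, so list length cannot be told apart from a wider occupancy of G159R, and neither can differences in protein level, which were not analysed here.

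The third pattern is the separation of the strongest thymocyte regions by genotype. The real split gave 0.186 and the highest other 0.05002 (1 of 18 splits as large), and 18 splits are too few for a share under 0.05. In equal-length lists, 1234 regions were restricted to homozygous Aiolos libraries. Of these, 47.3% were in the lists of both homozygous Ikaros libraries and 2.67% in those of both wild-type Ikaros libraries. In the full lists these shares were 6.91% and 1.95% of 3431 regions. Over all homozygous Aiolos regions, the share in both homozygous Ikaros libraries was higher, 73.5% in equal-length lists and 58.0% in full lists. The low wild-type shares follow in part from choosing regions without a wild-type Aiolos call, since calls of the proteins largely coincide. A shared preparation or input within a genotype cannot be told apart from joint occupancy by both proteins, since either could give more sharing within the genotype.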

How the results depend on the processing

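Thinning, the term for Y-linked reads and leaving out X- and Y-linked genes were chosen after seeing the data. The number of changed pre-B genes stayed within 1.5 times of 4176 under every alternative run except a log2 fold change of at least 1, which left 858 genes, 336 higher and 522 lower, by its construction. Without each library it ran from 2916 to 4212 (1479 to 2090 higher, 1437 to 2122 lower). Immunoglobulin constant and variable symbols numbered 0 in the table, so leaving them out moved nothing. The replicate numbers did not pair the pre-B libraries (r = -0.006, -0.022 and -0.032 across genes between same-numbered libraries), and with the replicate block 4087 genes and 1 list were called. Camera called 1 list with at least 10 CPM in 3 libraries, 1 after thinning, 1 with the term for Y-linked reads, which rests on heterozygous replicate 2 alone, in each case the immediate-early list, as with the block, 0 to 2 without each library, and fry called 5. With an estimated correlation the immediate-early list had adjusted p = 0.787 to 0.955 in these settings. The 5 fry calls were lost with the block (fry adjusted p = 0.0622 to 0.166). For single named genes and lists, 1607 of 1653 values kept their side of the threshold, 28 lost and 18 gained a call, and 0 reversed. The Aiolos log2 peak ratio was -0.20 with fold enrichment of at least 5, and without each library it ran from -0.37 to -0.21, and for Ikaros from -0.98 to -0.05. The shares of thymocyte regions moved beyond their counting intervals, and the cause was not tested except that leaving out a library loosens the requirement of a call in both. In the order wild-type Aiolos regions in homozygous, the reverse, wild-type Ikaros regions in homozygous, the reverse, they were 76.8%, 80.9%, 66.0% and 89.1% with −log10 q of at least 5, 78.8%, 81.5%, 63.6% and 90.2% with fold enrichment of at least 5, 57.1%, 54.7%, 62.3% and 62.2% with equal-length lists, and 57.1%, 63.3%, 45.9% and 74.4% with summit-based regions. Without each library they ran from 46.8% to 82.05%, 56.7% to 89.4%, 36.9% to 85.4% and 55.9% to 94.9%. Shares of regions also called for the other protein follow in the order Ikaros in Aiolos and Aiolos in Ikaros, for wild-type and then for homozygous cells. They were 89.0%, 75.5%, 96.4% and 63.8% with −log10 q of at least 5, and 90.9%, 79.0%, 97.9% and 62.1% with fold enrichment of at least 5. With equal-length lists they were 83.0%, 77.9%, 81.7% and 73.5%, and with summit-based regions 65.5%, 60.6%, 77.4% and 49.0%. Without each library they ran from 55.8% to 93.3%, 45.5% to 82.8%, 62.7% to 97.1% and 39.5% to 89.4%. The within-genotype minus between-genotype Jaccard index in thymocytes ran from 0.0255 to 0.0369 without each library, and without any 1 of the 4 Aiolos libraries another split was larger (exact permutation p = 0.111). For NALM-6, paired by replicate number (replicate block), the log2 difference in peaks was 2.23 and its exact sign-flip test was at the smallest p that 16 assignments can give, which is above 0.05. In these lists same-numbered libraries had a mean Jaccard index of 0.231 and others 0.216. Without each library the difference ran from 1.60 to 2.59 and the Jaccard difference from 0.265 to 0.375. Regions in all 8 libraries numbered 2248 with −log10 q of at least 5 and those only in G159R 10984 with fold enrichment of at least 5. In equal-length lists, which leave out weaker peaks, 1727 were only in those of G159R, 1083 only in those of WT and 925 in all 8. With summit-based regions 386 were only in WT. Without each library the 3 classes ran from 21322 to 26181, 87 to 282 and 3480 to 12537. For these NALM-6 values the cause was not tested. The motif, word, gene panel and RNA-with-peak alternatives were not run.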

Other observations

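All tests in this part were chosen after the results were seen. Genotype-restricted thymocyte regions of 1 protein were compared with the other protein. Of 6026 regions called in both wild-type and no homozygous Aiolos library, 26.4% were called in both wild-type and 1.66% in both homozygous Ikaros libraries. Of 612 regions called in both homozygous and no wild-type Ikaros library, 80.2% were called in both homozygous and 24.7% in both wild-type Aiolos libraries. Of 4251 regions restricted to wild-type Ikaros libraries, 44.2% were called in both wild-type and 12.35% in both homozygous Aiolos libraries. Of 3431 regions restricted to homozygous Aiolos libraries, 6.91% were called in both homozygous and 1.95% in both wild-type Ikaros libraries. Over all regions, the share called in both libraries of the other protein and same genotype was 73.9% for wild-type Aiolos and 86.2% for wild-type Ikaros. For homozygous cells it was 58.0% for Aiolos and 94.7% for Ikaros. Each restricted class was thus shared less within its genotype than all regions were. No test of these shares was run.

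Strain variants linked to the edited allele may raise the number of changed genes near Ikzf3. Of the 100 tested genes nearest to Ikzf3 on chromosome 11, 10 (10%) changed by at least 1 on the log2 scale, against 858 (7.24%) of 11851 tested genes (two-sided Fisher exact p = 0.328). The p-value did not pass 0.05, which does not exclude a small excess.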
